A study of Mus musculus with 2 samples.

How the data were processed

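The series holds neural stem cells cultured from the hippocampus of male mice and sorted singly into 2 plates of 384 wells by autofluorescence gate. Per the labels' protocols, cells were lysed by heat, the barcoded material of a plate was pooled into 1 library and amplified by in vitro transcription, and libraries were made by SORT-seq and CEL-Seq2 and sequenced with 26 cycles of read 1 and 60 of read 2. Per the submitters' processing notes, BWA 0.7.15, R 4.2.0 and Seurat 4.1.1 were used and the builds hg19 and mm10 were named, without a role for either.

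The authors deposited 1 table per plate, a merged table of kept cells and a table of each cell's properties. The plate tables and the merged table hold an expected count in each entry: deposited values are molecule counts corrected for molecules that share 1 of 4096 identifiers, and inverting that correction gave whole identifier counts to within 1e-06 in every entry. The merged table of 15364 genes equalled the plate tables to within 0.0001 for every kept cell, without spike-ins. Per the file headers the authors' per-cell table gives the total expected count, the count of genes seen, the percent of counts in mitochondrial and ribosomal protein genes, a score for S, G2/M and G0 genes, phase, cluster, condition and gate, and the intensity of scatter and fluorescence channels in arbitrary units. How the authors filtered cells and set phases and clusters is not stated in the labels. Of the wells, 128 were outside the per-cell table and were left out, since no condition or gate is given for them.

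Between conditions, the counts of all kept cells were summed per culture, with 174, 151, 151 and 164 cells in the quiescent, 24 h exit, 48 h exit and activated cultures, and divided by the sum's total to give CPM. Log2 ratios were taken with 10 CPM added, with exact 95% Poisson intervals on each sum and an exact conditional binomial interval on the ratio. These cover counting error only. Each condition had 1 culture, and cells are not replicates of a condition, so no test was made. For 33 lists of genes the median log2 ratio over members with at least 20 counts was set among 10000 random lists of equal size matched on mean expression, which gives a percentile and no p. Shares of cells with a transcript were taken after thinning every cell to the 10th percentile of totals, with exact binomial intervals. The named genes, by a rule, were the 8 largest log2 ratios in each direction among genes with at least 100 counts and a count in 10% of cells, leaving out mitochondrial, ribosomal protein and predicted genes, and 2 members of each list, with Mki67, Egfr, Id3, Gfap, Lamp1 and Ctsd always named. Between gates they were the 10 largest called changes in each direction and the 3 members of each called list with the smallest p. Some genes that the rule names are not reported here, and none was put in their place.

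Between the highest and lowest gates, counts were summed per culture and gate, rounded and tested with edgeR 4.0.16 under R 4.3.3 (TMM, filterByExpr, quasi-likelihood test, culture as a block, Benjamini-Hochberg at 0.05). The unit of replication was the culture, 4 in all, with 3 residual degrees of freedom, a common biological coefficient of variation of 0.124 and a median prior of 24.2 degrees of freedom. The 4 cultures are of 4 different states, so a change common to them was sought. On totals, the median log2 ratio of all genes was -0.03, -0.19, -0.06 and -0.16 in the activated, quiescent, 24 h and 48 h cultures, and TMM brought it within 0.02 of 0. Lists were tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry, on voom values from limma 3.58.1. DESeq2 1.42.0 was an alternative and gave no adjusted p for 6777 of 8739 genes. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

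Groups, comparisons, tests, lists, the naming rule and most alternatives were chosen before the data were examined. The use of whole identifier counts and leaving out Rn45s, the ribosomal RNA precursor, from the totals were chosen after seeing the data. Kept cells above the median total stood in for the planned use of all wells with 1000 transcripts, which could not be run for want of labels on the other wells.

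The methods were tested on simulated data. In the gate test 30.4% of genes changed 1.5-fold, 78.8% of those changed 2-fold and 98.7% of those changed 4-fold were recovered, with 8 false calls in 8615 genes. Each simulated fold was the same in every culture, so these shares do not cover gate effects that differ by culture. Between conditions, the intervals held the true ratio for 97.0%, 95.8% and 95.2% of genes changed 1.5-, 2- and 4-fold. A list raised on purpose lay at percentile 100, and 14 of 400 unchanged lists lay outside the central 95%. Reads of genes with near-identical copies, such as ribosomal proteins, tubulins, ferritins and metallothioneins, cannot be assigned to 1 copy with certainty.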

Results

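Neural stem cells from the hippocampus of male C57BL6/J mice aged 6 weeks were grown in culture, sorted singly by flow cytometry and profiled for polyadenylated RNA by SORT-seq, a plate method that tags each transcript with a molecular identifier at its 3' end. The labels name 4 states. Activated cells were grown with 20 ng/mL of FGF2 and EGF. Quiescent cells were held with 50 ng/mL of BMP4 and FGF2 without EGF and were considered quiescent after 3 days. The 24 h and 48 h exit cells had been returned from quiescence to activation medium with 0.5 ug/mL of noggin, a secreted antagonist of BMP4. Cells of each state came from 4 sort gates, here called low, low-mid, mid-high and high, set along the intensity of punctate autofluorescence, the light that cells emit without any dye.

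One culture per state was measured, so no difference between states has a replicate check. The quiescent and 24 h exit cultures shared 1 plate of 384 wells and the activated and 48 h exit cultures shared the other. The per-cell table held 640 cells, of which 174 were quiescent, 164 activated, 151 from 24 h exit and 151 from 48 h exit, with 32 to 46 cells per gate and state, where the labels give 47 cells per condition. Total transcript counts were 4815934 in the quiescent culture, 3046628 at 24 h, 4125228 at 48 h and 6563487 in the activated culture, and single cells held between 5013 and 97009 transcripts.

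Activated cells carried the most RNA. Their median was 35946 transcripts per cell, against 25137 in quiescent cells, 19270 at 24 h and 24947 at 48 h. Relative to the external ERCC spike-in RNA added to each well, the medians were 118 transcripts per spike-in count in activated cells, 73.3 in quiescent cells, 54.2 at 24 h and 81.3 at 48 h. Ribosomal protein transcripts made up a median 6.54% of a cell's counts in the activated culture, 2.51% in the quiescent one, 2.19% at 24 h and 3.98% at 48 h. Median side scatter of activated cells was 0.351 times that of quiescent cells, and their median autofluorescence was 0.756 times. The 24 h and 48 h cultures had 0.999 and 0.968 times the median autofluorescence of quiescent cells, and 48 h cells had 1.28 times that of activated cells. These are medians of kept cells, which were sampled by autofluorescence gate and kept in unlike numbers per gate, so they are not medians of the whole cultures. The activated and quiescent cultures were also on different plates. Levels below are shares of a culture's total counts. Activated cells had 1.61 times the transcripts per spike-in count of quiescent cells, so a lower share need not mean fewer transcripts per cell.

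The first comparison, activated against quiescent cells, asked how cells held with BMP4 and FGF2 without EGF differed from cells grown in EGF and FGF2. In activated cells the transcripts of division stood far higher. Ccnd1, a cyclin that drives cells through the G1 phase, was at 1103 CPM (counts scaled to a total common to all cultures) against 44.9 in quiescent cells. Mki67, a marker of cycling cells, was at 333 against 36.2 CPM, and Nes, an intermediate filament of neural progenitors, at 657 against 56.9 CPM. Quiescent cells carried instead Ncan, the matrix proteoglycan neurocan, at 9241 against 82 CPM, and Apoe, a lipid carrier, at 746 against 10.4 CPM. Nog, which encodes noggin, was at 229 CPM in quiescent cells and had no count in activated cells, where a floor of 3 counts over the culture makes it at least 502-fold lower.

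The largest log2 ratios towards activated cells, of CPM with 10 added, were those of Mest, an imprinted gene, at 4.94 (95% interval 4.80 to 5.10), Rab3b, a GTPase of vesicle release, at 4.85 (4.62 to 5.05), and Trp53i11 at 4.74 (4.54 to 4.93). Ccnd1 at 4.34, galectin gene Lgals1 at 4.13, the peptide hormone gene Adm at 4.03, the POU transcription factor Pou3f1 at 3.71 and the actin-binding Tagln2 at 3.44 followed. Among the largest towards quiescent cells were Ncan at -6.65 (-6.76 to -6.54), Ptchd2 at -6.29, the matricellular gene Sparcl1 at -6.13, the cholesterol acyltransferase Lcat at -6.05, Serpinf1 at -6.0, Apoe at -5.21 and Scrg1 at -4.80. These 15 genes had the same sign in each of the 4 gates, and their intervals cover counting error only.

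Gene lists fixed beforehand separated the same cultures. All 51 measured G2/M genes were higher in activated cells, with a median log2 ratio of 2.06, as were all 45 G1/S genes with a median of 1.48. Cyclin B1 gene Ccnb1 at 3.13, Ccna2 at 3.06 and the ribonucleotide reductase gene Rrm2 at 2.84 led them. Of 31 activation genes 25 were higher (median 1.70), and of 34 quiescence genes 29 were lower (median -0.85). Of 17 astrocyte markers 15 were lower in activated cells (median -1.59), among them the calcium-binding S100b at -4.62, the water channel Aqp4 at -4.44 and the filament gene Gfap at -2.86. BMP response genes were lower in 17 of 18 (median -1.49), with the feedback inhibitor Smad6 at -3.42 and the helix-loop-helix gene Id3 at -1.08. Each of these medians lay beyond all 10000 random lists of matched expression. With 1 CPM added in place of 10, which widens ratios of genes with few counts, the BMP response median was -2.80.

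Genes of biosynthesis stood with division. All 59 ribosomal protein genes (median 1.31; Rpsa 1.98), all 33 ribosome biogenesis genes (median 1.17; Nop56 2.08) and all 23 cholesterol biosynthesis genes (median 1.23; Fdps 2.37) were higher in activated cells. Cytosolic chaperones were higher in 22 of 27 (median 0.95; chaperonin gene Cct5 1.64), and chromatin packaging factors in 27 of 31 (median 1.26; the histone variant gene H2afz 2.28). Lysosome genes were lower in 53 of 62 (median -0.57, percentile 0), with the proteases Lgmn at -2.42, Ctsb at -1.79 and Ctsd at -1.71 and the membrane protein gene Lamp1 at -1.17. Autophagy genes (median -0.45, percentile 0.0200; Wipi1 -2.22) and fatty acid oxidation genes (median -0.35, percentile 0.155; the lipid chaperone Fabp5 -1.43) were lower too. Nuclear genes of oxidative phosphorylation had a median of 0.01 (percentile 9.75), and glycolysis genes one of -0.01 (percentile 25.6). Egfr, the EGF receptor, was at 1.42 (95% interval 1.18 to 1.65). Plate and state cannot be told apart here, since the cultures were on different plates.

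**Figure D1:**
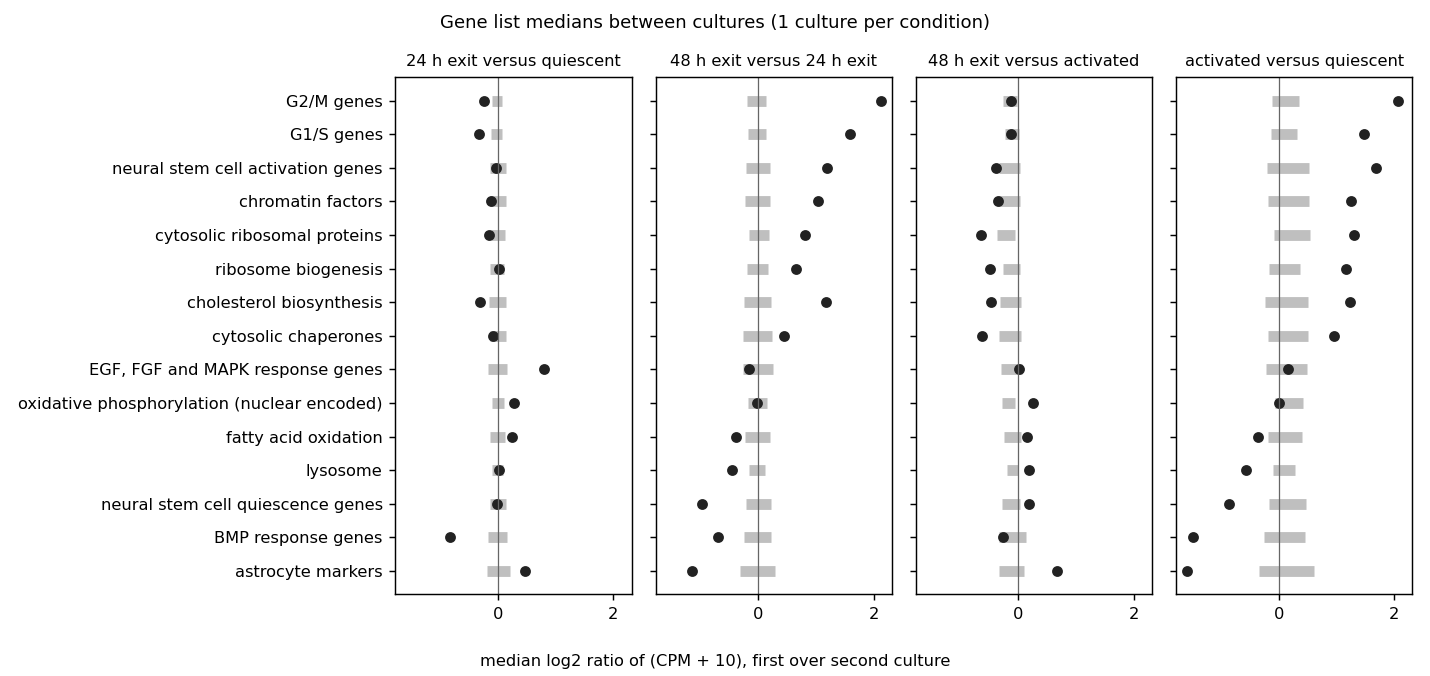
Median log2 ratio of CPM with 10 added for 15 gene lists in 4 comparisons (points), with the central 95% of medians of 10000 random lists matched on expression (grey bars); each line is a list and each panel compares a pair of cultures. G2/M genes lie at 2.06 in activated against quiescent cells and at 2.13 in 48 h against 24 h exit, and BMP response genes lie below 0 in all 4 panels.

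The second comparison, 24 h exit against quiescent cells, was made on 1 plate and asked how cells differed after the first day in activation medium with noggin. Loss of BMP4, return of EGF and the added noggin cannot be told apart here. At 24 h several targets of BMP signalling stood far below their quiescent level while Mki67 stood near it. Nog was at 8.21 CPM against 229, Smad6 at 4.92 against 98.9 and Id3 at 233 against 846. Genes that answer growth factors were higher, such as Spry4, a feedback inhibitor of receptor tyrosine kinases, at 428 against 129.6 CPM, Ccnd1 at 235 against 44.9 and Egfr at 45.3 against 17.2. Mki67 was at 35.9 against 36.2 CPM, a log2 ratio of -0.01 with a counting interval of -0.29 to 0.27.

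The largest log2 ratios towards 24 h were those of Pou3f1 at 2.86 (95% interval 2.61 to 3.10), the glycerol phosphate dehydrogenase Gpd1 at 2.63 (2.39 to 2.86), the peptide hormone gene Apln at 2.61, the long non-coding RNA Neat1 at 2.57, Clic5 at 2.42, the metallothionein gene Mt1 at 2.33, the transcription factor Hlf at 2.19 and Ccnd1 at 2.16. The lowest were Nog at -3.72 (-3.98 to -3.43), Ptchd2 at -3.48, Tmem158 at -3.41, Pmepa1, an inhibitor of SMAD signalling, at -3.22, Diras2 at -3.03, Inpp5j at -3.01, the taurine transporter Slc6a6 at -2.98 and the Wnt inhibitor Wif1 at -2.89. Each of these 16 kept its sign in all 4 gates.

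BMP response genes were lower in 15 of 18 (median -0.83, percentile 0, and -1.40 in the low gate alone), and genes of the EGF, FGF and MAPK response were higher in 16 of 20 (median 0.80, percentile 100). Quiescence genes parted: Hes5, a Notch target, was at -2.48 and Id3 at -1.81, while the list's median was -0.02. Notch pathway genes had a median of -0.36 (percentile 0.0200), with Hey1 at -1.79. Astrocyte markers were higher in 13 of 17 (median 0.47, percentile 100), such as the glutamate transporter Slc1a2 at 1.56 and the gap junction gene Gja1 at 1.53, although Gfap was at -1.59. Oligodendrocyte lineage markers were higher in 5 of 8 (median 0.39, percentile 99.8; the transcription factor gene Olig2 1.47), and neuron and neuroblast markers were lower in 6 of 10 (median -0.30, percentile 0.670; Tubb3 -1.55).

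As a share of counts, energy genes were higher at 24 h. Cells at 24 h held 0.74 times the transcripts per spike-in count of quiescent cells, so levels per cell need not be higher. Nuclear genes of oxidative phosphorylation were higher in 61 of 67 (median 0.28, percentile 100; complex I gene Ndufs1 0.56) and fatty acid oxidation genes in 24 of 29 (median 0.24, percentile 99.9; Cpt1a, the entry enzyme of mitochondrial oxidation, 1.07). Protein folding genes of the endoplasmic reticulum were lower in 17 of 25 (median -0.41; the chaperone Calr -1.47), as were matrix and adhesion genes in 27 of 36 (median -0.30; Tnc, tenascin C, -2.27), both at percentile 0. Lysosome genes had a median of 0.02 (percentile 67.1), with Lamp1 at 0.23 and Ctsd at -0.34. The G1/S median was -0.34, and the G2/M median was -0.24 but 0.044 on cells thinned to equal depth and 0.088 in the high gate, so its direction was not settled. Cholesterol biosynthesis had a median of -0.31 and ribosomal proteins one of -0.16, which were 0.068 and 0.12 in the low gate.

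The third comparison set 48 h against 24 h exit, the second day of exit. Division genes stood higher at 48 h. Rrm2 was at 254 CPM at 48 h against 15.1 at 24 h, Mki67 at 359 against 35.9, and Top2a, the topoisomerase of dividing cells, at 503 against 54.3. Genes of the quiescent state were lower, such as Apoe at 64.8 against 556 CPM and Aqp4 at 6.06 against 106. The 8 largest log2 ratios towards 48 h were those of Rrm2 at 3.39 (95% interval 3.12 to 3.66), the kinetochore gene Spc25 at 3.13, Ccna2 at 3.09, thymidine kinase gene Tk1 at 3.02, Mki67 at 3.01, Top2a at 3.00, Ccnb1 at 3.00 and Rab3b at 2.95. Among the lowest were Lcat at -3.52 (-3.72 to -3.33), Sparcl1 at -3.31, the clotting initiator F3 at -3.15, Neat1 at -2.94, Apoe at -2.92, Serpinf1 at -2.92 and Aqp4 at -2.85.

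All 51 G2/M genes (median 2.13), all 44 G1/S genes (1.59), all 57 ribosomal protein genes (0.82) and all 23 cholesterol biosynthesis genes (1.17) were higher at 48 h, each at percentile 100. Activation genes were higher in 25 of 30 (median 1.19), led by the tubulin regulator Stmn1 at 2.41, and chromatin factors in 28 of 31 (median 1.03; H2afx 2.81). All 17 astrocyte markers were lower (median -1.14), as were 30 of 33 quiescence genes (-0.98), 53 of 60 lysosome genes (-0.45; the protease Ctsl -1.69) and 15 of 16 BMP response genes (-0.70; Id2 -2.14), each at percentile 0. Fatty acid oxidation genes had a median of -0.39 (percentile 0.0400; Fabp5 -1.10), and the metallothionein genes Mt2 and Mt1 were at -2.54 and -1.79. These cultures were on different plates. For G2/M genes, 1 plate factor common to all of them was argued against as the whole cause. The log2 ratio of their sum per cell at the 90th percentile of cells exceeded that at the 10th by 2.15 (SD over gates 0.357). Plate factors that differ by gene stay open, since cells at the 2 percentiles may draw their sum from different G2/M genes. For the other genes plate and time cannot be told apart.

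The fourth comparison, 48 h exit against activated cells, was made on 1 plate and asked how far cells on the second day of exit had reached the activated state. The exit cells also had noggin in their medium, which is not named for the activated culture. Time since quiescence and the blocking of BMP4 therefore cannot be told apart here. Cell cycle genes were close: Mki67 was at 359 CPM against 333, a log2 ratio of 0.11 that was -0.062 in the low gate, and the G2/M median was -0.12 at percentile 64.5. Glial genes remained higher at 48 h, such as Slc1a2 at 291 against 17.1 CPM and Ncan at 709.7 against 82. Id3 was lower at 48 h than in the activated culture, at 99.5 against 395 CPM, and so was the intermediate filament gene Vim, at 844 against 3036. The largest log2 ratios towards 48 h were those of Slc1a2 at 3.48 (95% interval 3.29 to 3.66), Ncan at 2.97, the retinaldehyde dehydrogenase Aldh1a1 at 2.71, angiotensinogen gene Agt at 2.60, Cspg5 at 2.59, the sodium pump subunit Atp1b2 at 2.56, S100b at 2.55 and the adhesion gene Cntn1 at 2.51. Towards activated cells they were the microtubule gene Map1b at -3.02 (-3.25 to -2.77), Tnc at -2.91, Trp53i11 at -2.55, the imprinted gene Nnat at -2.46, calponin gene Cnn2 at -2.46, laminin gene Lamb1 at -2.41, the scaffold gene Akap12 at -2.37 and fibulin gene Fbln2 at -2.33.

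Biosynthesis genes were below their activated level at 48 h. None of 58 ribosomal protein genes was higher (median -0.65; Rps2 -0.98), nor any of 33 ribosome biogenesis genes (median -0.49; Gnl3 -0.94) or 31 proteasome genes (median -0.35; Psmc6 -0.81). Chaperones were lower in 24 of 25 (median -0.64) and cholesterol genes in 21 of 23 (median -0.48; Lss -0.96). Astrocyte markers were higher in 13 of 16 (median 0.66, percentile 100, and 1.03 with 1 CPM added), oxidative phosphorylation genes in 63 of 67 (median 0.26; Cox6c 0.81), mitochondrially encoded transcripts in 14 of 15 (median 0.52; mtCo3 0.89) and lysosome genes in 42 of 62 (median 0.18; Gm2a 2.03, Lamp1 0.64). On the same scale the median of all 10780 measured genes was -0.08, against 0.01 where mitochondrial and ribosomal protein genes were left out of the totals.

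Against quiescent cells, which were on the other plate, 48 h cells had the largest log2 ratios in Pou3f1 at 4.49 (95% interval 4.26 to 4.70), Ccnd1 at 4.25, lactoperoxidase gene Lpo at 3.61, Clic5 at 3.18, Apln at 3.04, Adm at 3.02, Mki67 at 3.00 and Wscd1 at 2.99. The lowest were Ptchd2 at -5.16, Lcat at -4.82, Serpinf1 at -4.65, Nog at -4.55 with 1 count at 48 h, Slc6a6 at -4.36, Inpp5j at -4.04, Aqp4 at -3.98 and Wif1 at -3.93. No BMP response gene of 18 was higher at 48 h (median -1.42; Id1 -3.71), whereas all 51 G2/M genes were (median 1.87). The medians of ribosomal proteins at 0.67, ribosome biogenesis at 0.76, cholesterol biosynthesis at 0.84, activation genes at 1.22, lysosome genes at -0.41 and matrix genes at -0.60 each lay beyond all 10000 random lists.

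**Figure D2:**
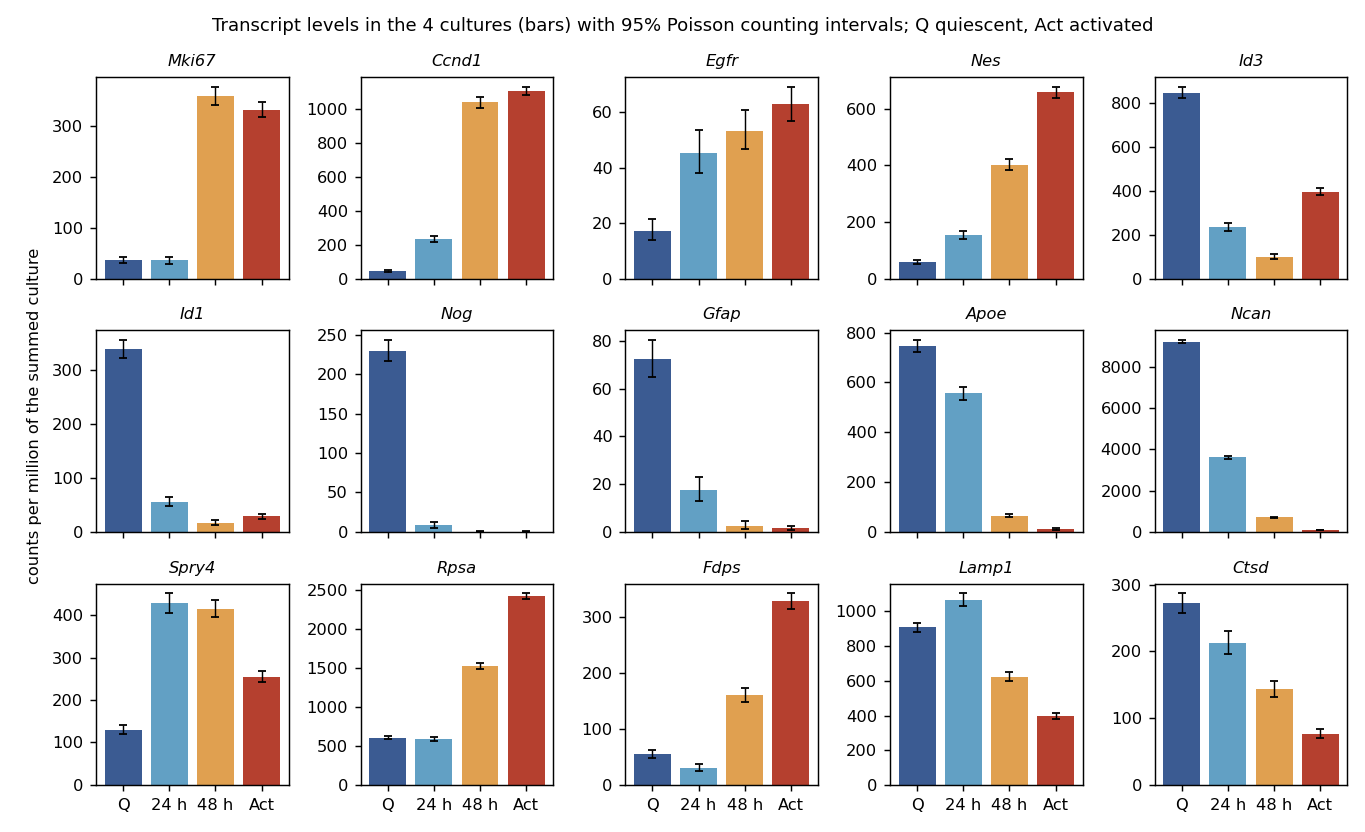
CPM of 15 genes in the summed cells of the quiescent (Q), 24 h exit, 48 h exit and activated (Act) cultures, on linear axes from 0; bars are 1 culture each and whiskers are 95% Poisson intervals for counting error. Nog and Id3 are lower at 24 h than in quiescence, whereas Mki67 is near 35.9 CPM at 24 h and 359 CPM at 48 h.

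Shares of cells with a transcript were compared after every cell was thinned to 12748 transcripts, which left out 18 quiescent, 29 of the 24 h, 11 of the 48 h and 6 activated cells. Mki67 was seen in 10.3% of 156 quiescent cells (exact 95% interval 5.98 to 16.1), 15.6% of 122 cells at 24 h (9.64 to 23.2), 72.1% of 140 cells at 48 h (63.9 to 79.4) and 81.6% of 158 activated cells (74.7 to 87.3). Before thinning these shares were 13.2%, 14.6%, 78.1% and 93.3%. Gfap was seen in 52.6% of quiescent cells, 12.3% at 24 h, 2.86% at 48 h and 1.90% of activated cells, and before thinning in 62.6%, 14.6%, 5.30% and 4.27%. Nog was seen in 71.2% of quiescent cells and 7.38% at 24 h, and in 0 of 158 activated cells, with an exact 95% upper limit of 2.31% on the share with a counted transcript, which does not limit the share of cells that express it below capture; before thinning its shares were 77%, 15.2% and 0 of 164 cells. Egfr was seen in 19.2% of quiescent cells, 43.4% at 24 h, 43.6% at 48 h and 53.8% of activated cells, against 30.5%, 53%, 67.5% and 84.8% before thinning. The material of all wells of a plate was pooled into 1 library, so transcripts carried over between wells would add to low shares.

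The authors' own cell classes followed the states. Their phase calls put 146 of 174 quiescent cells (83.9%, exact 95% interval 77.6 to 89) and 138 of 151 cells at 24 h (91.4%, 85.7 to 95.3) in G0, against 22 of 151 at 48 h (14.6%, 9.36 to 21.2) and 1 of 164 activated cells. Their cluster 1 held 166 quiescent cells, cluster 0 held 145 cells of 24 h exit, and cluster 2 held 163 activated cells. Of the 48 h cells, 109 lay in cluster 3 and 41 in cluster 0, beside the 24 h cells of the other plate. Within the 48 h culture, the G0 call was given to 0 of 42 cells of the low gate, 4 of 36 of the low-mid gate, 5 of 33 of the mid-high gate and 13 of 40 of the high gate (32.5%, exact 95% interval 18.6 to 49.1). Cluster 0 held 4 of 42, 9 of 36, 11 of 33 and 17 of 40 cells of those gates. How the authors set phase calls and clusters is not stated. Depth, which differed by gate, may bear on them, and this was not tested.

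The last question was how cells of high and low autofluorescence differ within a culture. The gates, not the cultures, are compared here, and each of the 4 cultures gives 1 contrast, so this is the only comparison with a test. Cells of the high gate were bigger by scatter and richer in RNA. Their median transcript total was 2.17 times that of the low gate in the activated culture, 2.14 in the quiescent one, 1.65 at 24 h and 1.65 at 48 h, and relative to spike-in counts the ratios were 2.12, 1.99, 1.5 and 1.46. Forward scatter, which grows with cell size, was 1.93, 1.86, 1.63 and 1.77 times as high in the same order of cultures, and side scatter 2.23, 2.42, 2.05 and 2.5 times. Median autofluorescence itself differed 2.93, 2.72, 2.88 and 3.21 times between the end gates.

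**Figure D3:**
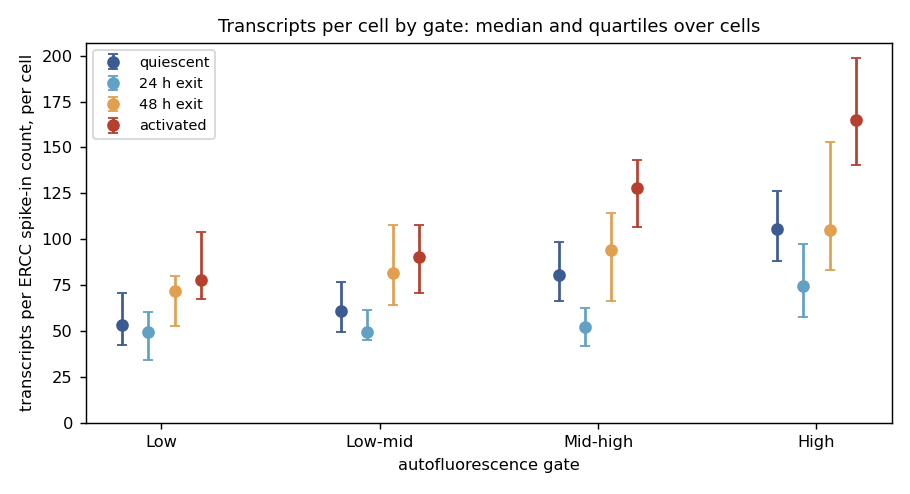
Transcripts per ERCC spike-in count in single cells (vertical axis) by autofluorescence gate (horizontal axis) in the 4 cultures; points are medians and whiskers lower and upper quartiles over cells. In the activated culture the median is 77.8 in the low gate and 165 in the high gate.

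On sums scaled by TMM factors, which set the bulk of genes near a ratio of 1, 256 of 8739 genes differed between the high and the low gate (edgeR's quasi-likelihood test, culture as a block, Benjamini-Hochberg adjusted p under 0.05), of which 188 rose and 68 fell. Rises and falls are relative to that bulk. The high gate held 1.46 to 2.12 times the transcripts per spike-in count, so a fall need not mean fewer transcripts per cell. Kpna2, a nuclear import receptor that peaks in G2, rose by 1.85 on the log2 scale (SE 0.16, adjusted p = 1.27e-07, higher in 4 of 4 cultures). Cdkn1a, the cell cycle inhibitor p21, rose by 1.52 (SE 0.17, adjusted p = 1.57e-04, 4 of 4), and the small heat shock protein gene Cryab by 1.27 (SE 0.14, adjusted p = 3.65e-06, 4 of 4). The zinc transporter gene Slc39a12 rose by 2.20 (SE 0.30) and S100b by 1.21 (SE 0.20), both in 4 of 4 cultures. Among genes that fell were the receptor tyrosine kinase gene Kit at -1.12 (SE 0.20, adjusted p = 0.00232), the snoRNP protein gene Nop56 at -0.71 (SE 0.13, adjusted p = 0.00232) and the chromatin protein gene Hmgn2 at -0.64 (SE 0.12, adjusted p = 0.00359), each lower in all 4 cultures.

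The largest rises took in also Serpina3n (2.34), Nek3 (2.10, higher in 3 of 4 cultures), the secreted chaperone Clu (1.87), neurexin gene Nrxn3 (1.72), cyclin F gene Ccnf (1.53) and Cdca2 (1.51), with adjusted p from 0.00129 to 0.0370. The 10 largest falls took in P2rx1, an ATP-gated channel gene (-1.89), lower in the quiescent and 24 h cultures and without a count in either gate of the others, carbonic anhydrase gene Car3 (-1.62, lower in 3 of 4 cultures), Mex3b (-1.38), the histone chaperone Npm3 (-1.04), tubulin gene Tuba1c (-1.03), the exosome subunit Exosc8 (-0.97), Pafah1b3 (-0.97), the snoRNA host gene Snhg4 (-0.95) and the arginine methyltransferase Prmt1 (-0.91), with adjusted p from 0.0114 to 0.0438. Of the genes named whatever their value, Ctsd rose by 0.72 (adjusted p = 0.00491, 4 of 4 cultures). Lamp1 at 0.41 (adjusted p = 0.0579), Gfap at 1.12 (0.0853), Mki67 at 0.32 (0.311), Egfr at 0.29 (0.518) and Id3 at 0.06 (0.931) did not pass.

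The calls leaned on 1 culture. Without the 48 h exit culture 25 genes were called, 24 of them among the 256, and without the activated culture 152 were called, 122 of them among the 256. Of 62 named genes that passed, 10 passed in all 4 fits that left out 1 culture: Slc39a12, Kpna2, Ccnf, Cdkn1a, Ube2c, S1pr1, Slc4a4, S100b, Cryab and Hist1h1c. DESeq2 called 123 genes, 107 of them among the 256, edgeR on cells thinned to 12748 transcripts called 199, 141 of them among the 256, and a linear trend over all 4 gates called 640, of which 246 were among the 256. The trend takes the 4 gates of a culture as separate units, so its count is not held to the spread between cultures. A model without culture as a block called 0 of 7792 genes with edgeR's quasi-likelihood test, with 115 at an unadjusted p under 0.05, since differences between cultures then count as noise.

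**Figure D4:**
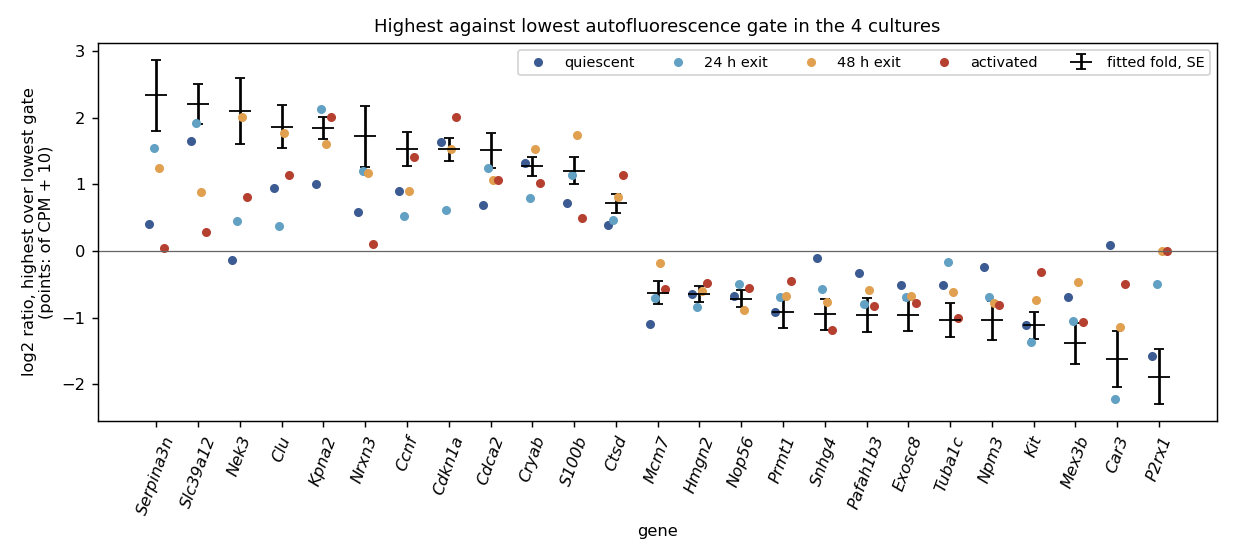
Log2 ratio of the high over the low autofluorescence gate (vertical axis) for 9 of the largest rises, the 10 largest falls and 6 list members (horizontal axis); bars with whiskers are the fitted fold and its SE, and points are the 4 cultures with 10 CPM added, which draws genes of few counts towards 0. Cdkn1a lies between 0.62 and 2.00 in the 4 cultures.

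With camera, a set test with a preset correlation between genes, 21 of 30 lists differed between the gates, 13 higher and 8 lower in the high gate, and none did with an estimated correlation, where adjusted p ran from 0.164 to 0.860. Fry, which asks whether a list's genes move one way on balance, called 6. These were activation genes, cell cycle inhibitors, fatty acid oxidation, glycolysis, antioxidant genes and chromatin factors. Without the activated, the quiescent or the 48 h culture fry called none of them. The activation list shares Hmgb1, Hmga2, Hmgn2, Dek and Ezh2 with chromatin factors, and Ncl, Npm1, Nolc1 and Fbl with ribosome biogenesis. Activation genes are therefore not a result separate from those lists. The estimated correlation was 0.83 for ribosomal proteins, 0.68 for mitochondrially encoded transcripts, 0.51 for cholesterol biosynthesis and 0.32 for astrocyte markers. It ran down to -0.033 for cell cycle inhibitors among called lists. Where it lies far above the preset value, the p with the preset correlation is too small. Camera's unadjusted p also grew where the estimate lay below the preset 0.01. It went from 6.96e-05 to 0.0249 for glycolysis (correlation 0.0031) and from 9.36e-07 to 0.0117 for fatty acid oxidation (-0.016). High correlation is therefore not the whole reason for the lost calls, and the preset p of any list may be too small. Below, the first adjusted p of a list is camera's with the preset correlation and the second its adjusted p with an estimated correlation. Astrocyte markers rose in the high gate (adjusted p = 7.92e-17, then 0.164): all 17 had a positive fold, 7 passed the test over all genes and 12 when adjusted over the list alone, among them Slc4a4 at 0.88 and the adhesion gene Hepacam at 0.78. Quiescence genes rose (adjusted p = 4.25e-13, then 0.181), with 8 of 33 passing over all genes and 15 higher and 1 lower when adjusted over the list alone, led by the lipid receptor S1pr1 at 0.99 and the metallothionein Mt3 at 0.89. The quiescence and astrocyte lists share members, such as Aqp4, Gfap and Slc1a2, so they are not separate results. Activation genes fell (adjusted p = 3.85e-05, then 0.164), with 5 of 29 passing and 9 lower and 1 higher when adjusted over the list alone, among them Cdk4 at -0.52 and Sox11 at -0.70; without the culture block the list did not pass (adjusted p = 0.0962).

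Lysosome genes rose as a list (adjusted p = 2.45e-05, then 0.257; median 0.15), with 9 of 55 passing when adjusted over the list alone and 3 over all genes, which were Ctsd, the ganglioside activator Gm2a at 0.68 and the protease Ctsh at 1.33. Autophagy genes rose (adjusted p = 0.0239, then 0.200), with 1 of 27 passing, Map1lc3b at 0.46, and 2 when adjusted over the list alone. The autophagy list did not pass without the 48 h culture (adjusted p = 0.0710), with the upper 2 against the lower 2 gates (0.0742) or without the culture block (0.0789), and Map1lc3b passed in none of the 4 fits that left out 1 culture. The lists of p53 targets (adjusted p = 1.93e-07, then 0.164; 4 of 18 over all genes, 6 over the list alone; Phlda3 1.09) and cell cycle inhibitors (adjusted p = 8.30e-04, then 0.164; 3 of 14 and 5; the retinoblastoma gene Rb1 0.82) rose. They share Cdkn1a, Ccng1 and Btg2, and Cdkn1a and Ccng1 are among the members that passed in both, so they are not separate results. The p53 medians were 0.45 in the activated, 0.27 in the quiescent, 0.018 in the 24 h and 0.48 in the 48 h culture. On plain totals the 24 h median was -0.063. G2/M genes rose (adjusted p = 0.00912, then 0.554), but their members parted: 5 of 51 passed over all genes, such as Ube2c at 1.20 and Aurkb at 1.36, and 10 were higher and 6 lower when adjusted over the list alone. The G2/M list did not pass on thinned cells (adjusted p = 0.129), without the quiescent culture (0.0720) or without the 48 h culture (0.132), and its median was -0.11 in the activated culture. G1/S genes fell (adjusted p = 2.58e-04, then 0.412; 2 of 43 over all genes and 8 over the list alone), with the replication helicase gene Mcm7 at -0.62 and the histone chaperone Nasp at -0.60. Their medians were -0.11 in the activated, -0.65 in the quiescent, -0.26 in the 24 h and 0.062 in the 48 h culture, the last being -0.14 on plain totals, and without the quiescent culture the list did not pass (adjusted p = 0.0990).

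For mitochondrially encoded transcripts all 15 members had a positive fold (adjusted p = 1.53e-17, then 0.181), 5 passed over all genes and 14 when adjusted over the list alone, such as mtNd5 at 0.53. Nuclear oxidative phosphorylation genes had a positive fold in 63 of 67 (adjusted p = 1.20e-10, then 0.327), yet 0 passed singly on either adjustment. Fatty acid oxidation (3.51e-06, then 0.164; 3 of 28 over all genes, 9 higher and 1 lower over the list alone; Hadhb 0.48), glycolysis (1.31e-04, then 0.164; 2 of 17 and 3; Ldhb 0.61), antioxidant genes (1.76e-04, then 0.164; 4 of 32 and 4; Gstm1 0.82) and matrix genes (5.35e-05, then 0.218; 8 of 32 and 10; Sparc 0.71) rose as well. Among lists that fell were ribosomal proteins (1.56e-17, then 0.327; 1 of 57 over all genes, 0 over the list alone; Rpsa -0.50), ribosome biogenesis (3.05e-14, then 0.199; 6 of 31 and 16), proteasome (2.63e-05, then 0.257; 0 of 31 on either adjustment) and cholesterol biosynthesis (3.85e-05, then 0.40; 1 of 23 and 3; Sqle -0.53). The ribosomal protein medians were -0.21 in the activated, 0.081 in the quiescent, -0.54 in the 24 h and -0.42 in the 48 h culture, and -0.26, -0.16, -0.63 and -0.65 on plain totals. The cholesterol medians were 0.061 in the activated, -0.045 in the quiescent, -0.75 in the 24 h and -0.74 in the 48 h culture, and without the 48 h culture that list did not pass (adjusted p = 0.0813). Cytosolic chaperones fell (3.85e-05, then 0.181; 1 lower and 1 higher of 24 over all genes, 5 and 1 over the list alone), with Cct6a at -0.53 against Cryab. Chromatin factors fell (2.12e-05, then 0.164; 4 lower and 1 higher of 31, 9 and 2 over the list alone), with Hmgb3 at -0.64 against the linker histone gene Hist1h1c at 0.74.

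The scale mattered for lists that rose. On plain totals 3 of the 13 had a median above 0 in all 4 cultures, which were astrocyte markers, mitochondrially encoded transcripts and cell cycle inhibitors, and the lysosome medians were 0.18, -0.10, -0.039 and 0.033 in the activated, quiescent, 24 h and 48 h cultures. Of the 8 lists that fell, 7 had a median below 0 in all 4.

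The other 9 lists did not pass with the preset correlation: BMP response (adjusted p = 0.818), EGF, FGF and MAPK response (0.155), neuron and neuroblast (0.738), oligodendrocyte lineage (0.0936), unfolded protein response (0.317), fatty acid synthesis and lipid droplets (0.725), Notch (0.692), immediate early (0.711) and interferon genes (0.179). Of these, BMP response genes passed without the quiescent culture (adjusted p = 0.00850), and oligodendrocyte (0.00762) and MAPK response genes (0.0482) passed without the 24 h culture. Of 18 microglia and macrophage, 22 endothelial, pericyte and fibroblast and 16 ependymal and choroid plexus markers, at most 2, 2 and 1 reached the count minimum in any pair of cultures, so those lists gave no median. An interaction of gate with plate called 0 of 8739 genes with edgeR's quasi-likelihood test, with 528 at an unadjusted p under 0.05; no other tool was run on it. Gates were filled into the wells of a plate in order, so gate, plate position and time of sorting go together in every culture.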

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

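The tests against depth in the gate comparison and against a plate factor in genes other than those of the cell cycle were chosen only after the result was seen. The wells outside the per-cell table held a signal of their own. Of these 128 wells, 17 carried 5000 or more transcripts, 10 on the plate of the quiescent and 24 h cultures and 7 on the other. Mitochondrial genes made up a median 47.9% and 45.2% of their counts, against 23.7% and 22.4% in kept cells of those plates. They have no condition or gate in the tables, so nothing further was asked of them.

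In 4 of 110 named genes, lists and ratios of per-cell medians tested between gates, 1 culture lay far from the other 3, and chance gives about 1 in 20 groups. These were the proteasome gene Psmc2, with a log2 ratio of -0.018 in the activated culture, the respiratory gene Uqcr11 at 0.19 and the lactate dehydrogenase gene Ldhb at 0.16 in the 24 h culture, and the ferritin gene Fth1 at 1.06 in the 48 h culture. No biological explanation was tested for them.

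The first pattern weighed was the 256 genes called between the high and the low gate. Of the 8 splits that part the gates of all 4 cultures, the real one included, 1 gave 256 genes, which was the real one, and the highest other gave 1. The 8 splits are too few for a share under 0.05. Depth as the whole cause was argued against. Cells with more transcripts were set against cells with fewer within each end gate, and the change per doubling, times the doublings between the gates, averaged -0.089 (SD over 8 sets 0.13) as a median over the called genes in the direction of the call, against a gate fold of 0.56 on plain totals with 10 CPM added. For size, forward scatter stood in. The median slope per doubling of autofluorescence in the direction of the call was 0.437 (SD 0.106) with forward scatter in the model and 0.401 without. This does not decide on size, since genes and directions came from the same gate contrast, which favours a slope on autofluorescence. Autofluorescence and forward scatter were also correlated, at 0.84 on average over the cultures. With forward scatter in the model the slope fell in the activated culture, from 0.351 to 0.293, and rose in the others. For a steady drift over the plate the value was -0.021 (SD 0.55) against a gate fold of 0.61, which met the margin set in advance narrowly. This does not decide on drift, since the sets had either sign. In the quiescent culture later wells of both end gates moved with the call, by 0.14 and 0.056 over about 1 row. Its gates lay 5.84 rows apart, with a fold of 0.53. In the activated culture both moved against it (-0.0010 and -0.11), and in the exit cultures the gates parted. Cell size, a drift over the plate, a step between gates, time of sorting and transfer between wells stay open, as does a biological difference in autofluorescence.

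The second pattern was the difference between plates in activated against quiescent and 48 h against 24 h cells. For G2/M genes, 1 plate factor common to all of them was argued against as the whole cause. The test used their sum per cell, so plate factors that differ by gene stay open. The log2 ratio of 48 h to 24 h cells was larger at the 90th percentile of cells than at the 10th by 2.15 (SD over gates 0.357). For the 15 genes named as among the largest between activated and quiescent cells, the median log2 ratio of 48 h to activated cells of the same plate, in the direction of the first difference, was -1.88 (SD over gates 0.589). These genes were chosen as extreme in the same activated culture, so a value below 0 decides nothing and a plate factor stays open for them. A plate factor under part of the G2/M difference cannot be excluded. At the 10th percentile of cells the log2 ratio was already 1.66 on average over the gates, against 3.81 at the 90th.

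The third pattern lay in the 48 h culture, whose high gate held 17 of 40 cells in the class of the 24 h cells, against 4 of 42 in the low gate. A lag of cells of higher autofluorescence in leaving quiescence was tested by the correlation across 8739 genes of the gate ratio with the 24 h against 48 h difference. It was 0.323 in the 48 h culture and 0.248 in the 24 h culture, the highest of the others, less than the 0.1 of separation set in advance. A lag and a gate difference common to all cultures cannot be told apart, because the other cultures share part of this axis.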

How the results depend on the processing

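Leaving Rn45s out of the totals and using whole identifier counts were chosen after the data were seen, and with them the gate test called 256 and 252 genes. Counted over all alternatives, list medians kept within their interval in 276 of 330 values for activated against quiescent cells, 276 of 330 for 24 h against quiescent, 263 of 329 for 48 h against activated, 273 of 329 for 48 h against 24 h and 278 of 330 for 48 h against quiescent, with 0, 4, 2, 1 and 0 turning direction. Named genes between conditions turned direction in 0 of 740, 4 of 770, 1 of 750, 2 of 680 and 0 of 710 values in that order. The cause was not tested for any change below unless stated.

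With 1 CPM added, which widens ratios of genes with few counts, medians in activated against quiescent cells were -0.80 for lysosome, 2.73 for G2/M, -2.80 for BMP response, -1.71 for astrocyte and 1.43 for cholesterol genes. At 24 h against quiescence they were -1.28 for BMP response and 0.94 for EGF, FGF and MAPK response. Astrocyte markers were at 1.03 in 48 h against activated cells, and G2/M genes at 2.89 against 24 h and 2.55 against quiescence. On thinned cells G2/M and astrocyte medians in activated cells were 2.27 and -1.44, the 24 h G2/M median turned to 0.044, and in 48 h against 24 h cells the cell cycle inhibitors turned to -0.024 and Ifitm2 to 0.011. Kept cells above the median total gave -0.60 for G2/M genes at 24 h.

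In the low gate alone, activated cells had a G2/M median of 2.36. At 24 h it gave -1.40 for BMP response and 0.65 for MAPK response, and ribosomal proteins turned to 0.12, cholesterol genes to 0.068, Rpl13a to 0.19, Psmd3 to 0.14 and Cyp51 to 0.030. In 48 h against activated cells it gave 0.51 for astrocyte markers and -0.44 for ribosomal proteins, and turned Mki67 to -0.062, while Hbegf turned to 0.59 against 24 h. In the high gate alone, activated cells had -1.14 for BMP response and 1.22 for ribosomal proteins. At 24 h it gave 0.71 for MAPK response and turned G2/M to 0.088 and Top2a to 0.16. In 48 h against activated cells it gave 0.81 for astrocyte markers and -0.86 for ribosomal proteins, and turned autophagy to -0.013 and glycolysis to -0.044.

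Totals without mitochondrial and ribosomal protein genes gave 0.82 for astrocyte markers in 48 h against activated cells, and 2.40 and 2.17 for G2/M genes in 48 h against 24 h and quiescent cells. TMM factors gave 1.21 for ribosomal proteins in activated cells. A count minimum of 100 gave -1.82 for BMP response in activated cells and 0.87 for astrocyte markers at 48 h against activated cells. Relative to spike-ins, transcripts per cell were 1.61 times as many in activated as in quiescent cells and 1.5 times at 48 h as at 24 h.

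The gate test called 123 genes with DESeq2, 442 with no filter beyond 1 count, 640 with a linear trend over the gates and 0 without culture as a block (edgeR's quasi-likelihood test, 115 at an unadjusted p under 0.05). The trend takes the gates of a culture as separate units. Leaving out each culture in turn gave 25 to 217 genes, and 18 to 23 lists by camera with the preset correlation. With an estimated correlation, camera's lowest adjusted p in those fits was 0.264. Fry's lowest adjusted p was 0.143 without the activated, 0.119 without the quiescent and 0.168 without the 48 h culture. Without the 24 h culture fry still called activation genes (0.0204), chromatin factors (0.0204) and fatty acid oxidation (0.0326). With every culture, camera with an estimated correlation called 0 lists and fry 6. In the fits that left out a culture Id3, which was not a called gene, ran from -0.21, without the 24 h culture, to 0.33 and so turned direction. Other alternatives gave 179 to 257 genes. Depth limits genes near the count minimum, as the intervals show.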

Other observations

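No test was made in this part, and its values were chosen after the tables were seen. The deposited percent of mitochondrial counts per cell equals the share of genes whose names carry a dash after mt, which are mitochondrial ribosomal and transfer RNAs. The mitochondrial messenger RNAs, such as mtNd5, are written without a dash and escape it. The deposited median over all cells was 7.02%, and with every mitochondrial gene counted it was 23.3%. By culture the medians were 5.42% and 19% in activated cells, 6.94% and 22.2% in quiescent cells, 8.11% and 26.2% at 24 h, and 8.88% and 28% at 48 h. The largest single cell value was 14.6% as deposited and 57.4% with every mitochondrial gene.

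The phase calls of activated cells differed by gate. The G2/M call was given to 24 of 34 cells of the low gate, 13 of 41 of the low-mid gate, 18 of 43 of the mid-high gate and 24 of 46 of the high gate. The G1 call was given to 0 of 34, 6 of 41, 8 of 43 and 9 of 46 cells in that order.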
